A study of Bos taurus with 64 samples.

How the data were processed

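MicroRNAs (miRNAs) were measured by sequencing in 64 libraries of skeletal muscle from Charolais and Holstein-Friesian steers. Per the labels' protocols, RNA was purified with the Qiagen RNeasy Plus Universal kit and libraries were made with an Illumina TruSeq stranded RNA kit. How small RNA was selected is not given in the sources used here. Per the submitters' processing notes, FastQC 0.11.8, cutadapt 2.6, R 3.4, edgeR 3.5 and the cattle build ARS-UCD 1.2 were used, without a stated role for each. The aligner, the miRNA counter and its annotation are not given in the sources used here.

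The authors deposited a single table of estimated counts, not normalized, with 1030 miRNA names and a column for each of the 64 libraries. Every column carried an animal number and phase that matched the description of 1 library, and 0 columns were left without a sample. Of the 1030 names, 226 were at 0 in all libraries and 61 held fractional values (more than 0.001 away from a whole number). In these, the values were whole multiples of 1 divided by a small integer, within 0.02 and with integers up to 12 tried. For 18 of the 61 that integer differed between the grass and the concentrate libraries, and 9 of those 18 entered the tests. Within a phase it differed between the breeds for 2 names on grass and 1 on concentrate. The values were rounded to whole counts before testing. miR-2285b had 3 empty cells and was left out. No name was repeated in the table. Pairs of names with nearly the same counts in every library may share reads or sequence, which was not examined, and their split is uncertain: miR-199a-3p with miR-199c (r = 1 across libraries), miR-10174-3p with miR-23b-3p, miR-2284aa with miR-2284z, miR-2284ac with miR-2285ai-5p, and miR-2285da with miR-2285dd and miR-2285bn. The gene table at hand is of another build, so no coordinates are printed. Names are those of the table without the species prefix bta.

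The libraries fell into 8 groups of 8 steers, from the labels: breed, residual feed intake (RFI, the feed eaten above or below that predicted for an animal's size and growth) high or low, and diet. Zero-grazed grass was the feed of the earlier phase and a high-concentrate diet that of the later phase. Diet can therefore not be separated from phase order, from age or from any difference in how the phases were processed or quantified. The 64 libraries came from 59 animals, 5 of which gave a library in both phases. The 5 animals' library pairs had correlations of 0.165, 0.398, 0.599, 0.288 and -0.111 in their deviations from the group means. The estimated correlation of libraries from an animal was 0.392. Pairing therefore comes from the animal numbers in the labels. The animal was not a block in the reported fit, and it was a random block or a fixed block in alternatives. The replicates were separate steers. The closest pair of libraries, from different groups, still differed far beyond counting noise (chi-square per degree of freedom 396), so no library was treated as a copy of another.

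Total counts per library ran from 4795950 to 12245155 with a median of 8143027. Intervals on shares of counts are 95% Wilson intervals, and they cover counting error only, since reads without molecular identifiers are not independent molecules.

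Differences were tested with edgeR 4.0.16 in R 4.3.3. TMM scaling factors were used and miRNAs were kept by filterByExpr over the 8 groups, which left 318. The names left out held 0.00575% of the counts. A quasi-likelihood model with robust dispersion was fitted to 8 group means (56 residual degrees of freedom), and 14 contrasts were tested from it. Contrasts are low minus high RFI, Holstein-Friesian minus Charolais, and concentrate minus grass. Changes were called at a Benjamini-Hochberg adjusted p of 0.05 within a contrast. Log2 differences are given ± standard error (SE) and CPM values (read counts scaled to a common library size, with TMM factors) as mean ± standard deviation (SD). Plots show log2 CPM without a prior count, while the Pearson and Spearman correlations use log2 CPM with a prior count of 2. All adjusted p-values of single miRNAs are from this edgeR test unless another tool is named. Groups of 8 were fitted across all miRNAs together, so these are model-based p-values.

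A set of 17 lists was tested: 10 of function and 7 of cell types that a muscle sample can hold. The lists of function were the myomiRs, the slow-fibre myosin-encoded miRNAs, regulators of myoblast proliferation and differentiation, lipid metabolism and adipogenesis, insulin and glucose signalling, hypoxia and mitochondrial function, the DLK1-DIO3 imprinted cluster, miR-17-92 with its paralogous clusters, let-7 with miR-98, and the ruminant miR-2284 and miR-2285 family. The cell-type lists were erythrocyte and platelet, leukocyte, endothelium, smooth muscle and fibroblast, epithelium, liver, and neuron and nerve. The list test was camera from limma 3.58.1 with a preset correlation of 0.01 between miRNAs, repeated with an estimated correlation, with adjustment over the lists within a comparison. The epithelium list had 1 tested member and was not tested as a list. In all, 37 miRNAs belong to more than 1 list. Member counts are given over all tested miRNAs and adjusted over the list alone.

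The text names miRNAs by a rule. For averaged comparisons it names the 8 largest called rises and falls at a mean of 10 CPM or more, and for comparisons within a breed or diet the 3 called with the smallest p. Where an RFI comparison called none, the 3 with the smallest p are named as not passing. It also names the 3 most abundant members of each list that passed, every tested myomiR for breed and diet, and the 5 most abundant miRNAs. Examples from lists that did not pass, the members of counts of 5 or fewer, and miR-451 wherever it was not called were chosen after their values were seen. The grouping, contrasts, tests, lists, naming rule and most alternatives were fixed before the data were examined. List tests were planned only for the RFI comparisons and their average, the breed average and the diet average. Those of breed within a diet, diet within a breed and the breed by diet interaction were outside that plan, as were the miRNAs named from them.

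The alternatives were other scalings (RLE size factors, total counts, and TMM without the 3 most abundant miRNAs), other filters on low counts, DESeq2 1.42.0, limma-voom, fits restricted to the groups compared, fits with the animal as a block, fits without libraries, and other thresholds. The tests were tested on simulated counts, 5 simulations for each of 3 comparisons with 40 of 318 miRNAs changed. For RFI in Holstein-Friesian steers on concentrate, the edgeR step recovered 37% of the miRNAs changed 1.5-fold and 77% of those changed 2-fold, and 6.56% of its calls were false. For the breed average it recovered 82% and 100%, with 5.70% false calls, and for the diet average 86% and 99%, with 6.57% false calls. On the diet average the list test recovered a changed list in 5 of 5 simulations and called 0 of 75 other lists. The simulated counts were drawn independently for each miRNA. They therefore say nothing on false calls where miRNAs vary together, nor on the preset correlation of the list test.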

Results

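Muscle miRNAs were counted in 64 libraries from growing steers of a beef breed, Charolais, and a dairy breed, Holstein-Friesian. Feed intake had been recorded in 90 Charolais and 77 Holstein-Friesian steers during 2 phases of 70 days, separated by 14 days of acclimatisation. Fresh perennial ryegrass was fed in the earlier phase and barley-based concentrate with a limited amount of silage in the later phase. From these steers 8 libraries were made for each combination of breed, RFI class and diet. A low-RFI animal eats less than predicted and is the more feed-efficient. Total counts ran from 4795950 to 12245155 per library (median 8143027), and each library held between 421 and 596 miRNAs with a count (median 492).

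miR-10b, a miRNA encoded within the HOXD gene cluster, was the most abundant miRNA and took 56.8% ± 8.999 of the counts (SD, n = 64). Its share ran from 19.3% in high-RFI Holstein-Friesian grass replicate 1 (95% Wilson interval 19.32 to 19.36) to 74.5% in low-RFI Holstein-Friesian concentrate replicate 3 (74.51 to 74.57). It was followed by miR-486 at 10.3% ± 2.56, miR-133a at 7.52% ± 2.604, miR-26a at 4.83% ± 1.54 and miR-143 at 2.92% ± 1.75 (SD, n = 64). miR-486 and miR-133a are enriched in striated muscle, and miR-143 is best known from smooth muscle. The 5 most abundant miRNAs together held 82.4% of the counts and the 20 most abundant 94.6%. Among the other muscle miRNAs, miR-133b averaged 8983 CPM, the myosin-encoded miR-208b and miR-499 825 and 346 CPM, miR-1 247 CPM and miR-206 14.6 CPM. TMM scaling factors ran from 0.511 to 2.43.

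**Figure D1:**
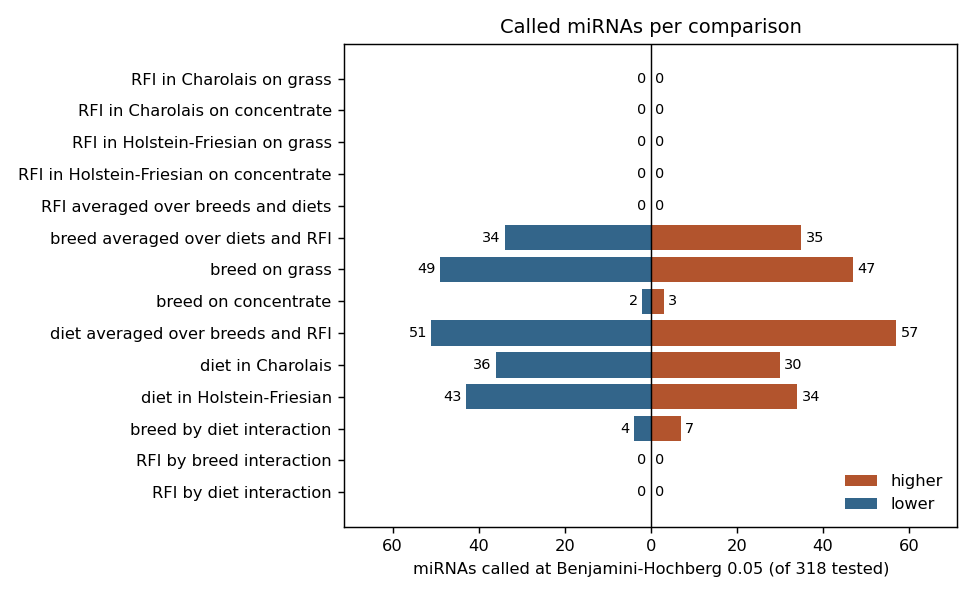
Number of miRNAs called at a Benjamini-Hochberg adjusted p of 0.05 by edgeR in each of the 14 comparisons, of 318 tested, with bars to the right for miRNAs higher and to the left for miRNAs lower in low RFI, in Holstein-Friesian or on concentrate. The RFI comparisons and their interactions have 0 calls, the diet average 57 higher and 51 lower (7 and 118 with total-count scaling), and the breed average 35 higher and 34 lower (37 and 3 with total-count scaling).

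The comparison of low with high RFI asked which muscle miRNAs go with feed efficiency. No miRNA passed the test in any breed and diet. In Holstein-Friesian steers on concentrate the smallest p-values belonged to the lymphocyte miRNA miR-150 (log2 difference -0.87 ± 0.23), miR-362-3p (-0.63 ± 0.18) and miR-342 (-0.41 ± 0.12), each with an adjusted p of 0.0943 and each lower in 8 of 8 low-RFI libraries than the high-RFI median. On grass in the same breed they belonged to miR-21-5p, abundant in fibroblasts (0.87 ± 0.23, adjusted p = 0.126, higher in 5 of 8), miR-455-3p (0.75 ± 0.22, adjusted p = 0.242, 8 of 8) and the smooth muscle miRNA miR-143 (0.61 ± 0.22, adjusted p = 0.653, 5 of 8, and 0.30 without the 2 libraries far from their groups in miR-143). In Charolais steers on grass the nearest were miR-149-5p (0.57 ± 0.20), miR-146b (-0.78 ± 0.30) and miR-379 (-0.63 ± 0.26), all with an adjusted p of 0.86. In Charolais steers on concentrate they were miR-379 (-0.72 ± 0.26), miR-1307 (-0.34 ± 0.13) and miR-2419-5p (1.45 ± 0.60), all with an adjusted p of 0.861. The imprinted-cluster miRNA miR-379 was lower in 8 of 8 low-RFI Charolais libraries than the high-RFI median on both diets. It was picked by its small p, and some Charolais steers gave libraries on both diets, so the 2 counts are not independent support.

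By edgeR the calls numbered 0 for Charolais on grass, Charolais on concentrate, Holstein-Friesian on grass, Holstein-Friesian on concentrate and the average, with 15, 10, 17, 34 and 11 of 318 miRNAs at an unadjusted p under 0.05, where 15.9 would be expected by chance. DESeq2 and limma-voom also called 0 in each. Leaving out single libraries kept the count at 0 except in Holstein-Friesian steers on concentrate. There, without high-RFI replicate 1, 4 miRNAs passed: miR-150, miR-342, miR-28 (0.46) and miR-7 (1.13), all at an adjusted p of 0.0427. miR-28 also passed without high-RFI replicate 5 (adjusted p = 0.0479) and without replicate 7 (0.0385). Without the concentrate libraries of the 5 steers sampled in both phases, miR-150 (-0.96) and miR-342 (-0.47) passed, each with an adjusted p of 0.0311. Of those libraries only high-RFI replicate 1 is Holstein-Friesian, so this fit dropped the same library from the comparison and is not separate support.

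Some lists shifted between RFI classes as a whole although 0 of their members passed alone, and none of these shifts held with an estimated correlation. The median of each such list kept its sign under the other 3 scalings. In Charolais steers on concentrate the myomiRs (camera adjusted p = 0.0204, 0.363 with an estimated correlation) and the liver list (0.0204, 0.342 with an estimated correlation) lay lower in low RFI. The lipid metabolism list (0.038, 0.342 with an estimated correlation) and the miR-17-92 clusters (0.00328, 0.432 with an estimated correlation) lay higher. The most abundant myomiRs stood at -0.14 (miR-486), -0.17 (miR-133a) and -0.24 (miR-133b), and the liver members at -0.23 (miR-192), -0.31 (miR-885) and -0.23 (miR-194). Of the 3 most abundant lipid members, 2 went against the list, miR-143 at -0.03 and miR-378 at -0.24, and miR-27b stood at 0.17. Those of the miR-17-92 clusters stood at 0.26 (miR-92a), 0.19 (miR-25) and 0.33 (miR-19b). In Holstein-Friesian steers on concentrate the miR-17-92 clusters, which drive cell proliferation, lay lower (median -0.53, camera adjusted p = 0.000882, adjusted p = 0.874 with an estimated correlation), with miR-92a at -0.21, miR-25 at -0.36 and miR-19b at -0.47. The erythrocyte miRNA miR-451 stood at 0.49 ± 0.73 in that Charolais comparison and at -0.94 ± 0.73 (adjusted p = 0.686) in that Holstein-Friesian comparison. In the average over breeds and diets the slow-fibre pair lay lower, with miR-208b at -0.12 ± 0.10 and miR-499 at -0.23 ± 0.13 (camera adjusted p = 0.0307, adjusted p = 0.413 with an estimated correlation). The leukocyte list did so too (0.0307, adjusted p = 0.48 with an estimated correlation), with miR-142-5p at -0.19, miR-342 at -0.05 and miR-146a at -0.23. On grass, miR-451 averaged 3092 ± 3395 CPM in low and 3584 ± 3680 in high RFI in Charolais steers. In Holstein-Friesian steers on grass it averaged 3128 ± 3398 and 3682 ± 2166 (SD, n = 8 each). The difference of the RFI effects between breeds and between diets gave 0 calls by edgeR (32 and 14 miRNAs at an unadjusted p under 0.05), DESeq2 and limma-voom.

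Breed asked how muscle of the dairy breed differs from that of the beef breed. miR-206, a skeletal-muscle miRNA that promotes myoblast differentiation, was 1.86-fold higher in Holstein-Friesian steers (log2 0.89 ± 0.16, adjusted p = 6.38e-05), at 19.0 ± 8.96 CPM against 10.1 ± 5.22 (SD, n = 32 each), and above the Charolais median in 28 of 32 libraries. miR-146a, a feedback inhibitor of innate immune signalling, was 1.63-fold higher (log2 0.70, 41.3 ± 17.8 CPM in Charolais and 66.0 ± 30.7 in Holstein-Friesian, adjusted p = 0.00114, 25 of 32), and miR-146b (0.51) and the lymphocyte miRNA miR-155 (0.44) were higher with it. miR-486 was lower by a log2 difference of -0.46 ± 0.10 (adjusted p = 0.000673, 26 of 32). miR-101, a regulator of the histone methyltransferase EZH2, was lower at 2470 ± 414 CPM against 3206 ± 569 (-0.37 ± 0.06, adjusted p = 4.9e-05, 30 of 32). The liver-enriched miR-885 was lower by -0.61 ± 0.15 (28 of 32).

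The other large differences were miR-708 (0.62), miR-409a (0.54), miR-199a-5p (0.45) and miR-2285k (0.44) among the higher, and miR-215 (-0.57 ± 0.21, adjusted p = 0.044), miR-484 (-0.37), miR-331-3p (-0.35), miR-15a (-0.34) and miR-22-3p (-0.32) among the lower. The remaining myomiRs did not pass: miR-133a -0.24 (adjusted p = 0.086), miR-133b -0.22, miR-208a -0.73 (adjusted p = 0.0683), miR-208b -0.07, miR-499 0.04 and miR-1 at 0.00 to 2 decimals. Thus of the 8 myomiRs 1 was higher and 1 lower (1 and 2 adjusted over the list alone).

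**Figure D2:**
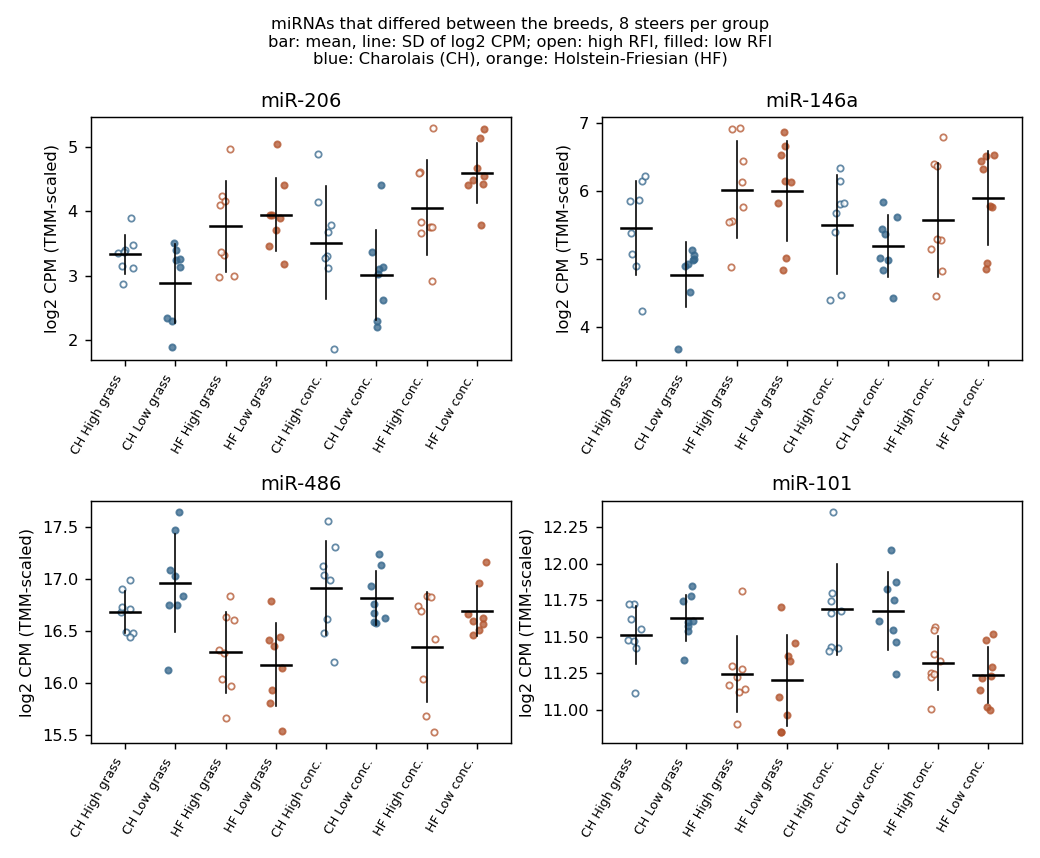
Log2 CPM (TMM-scaled) of miR-206, miR-146a, miR-486 and miR-101 in each library by group, with 8 steers per group and points open for high and filled for low RFI, where bars mark group means and lines the SD. The low-RFI Holstein-Friesian group on concentrate averaged 25.3 ± 8.15 CPM of miR-206 and the low-RFI Charolais group on concentrate 9.09 ± 5.29, while miR-101 lay below the Charolais median in 30 of 32 Holstein-Friesian libraries (its breed call is lost with total-count scaling).

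In the DLK1-DIO3 imprinted cluster, a maternally expressed group of miRNAs tied to fetal growth and muscle mass, 7 of 26 tested members were higher in Holstein-Friesian steers and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.26. miR-127, its most abundant member, was higher by 0.24, and miR-411a (0.18) and miR-381 (0.05) did not pass. The cluster passed the list test (camera adjusted p = 4.53e-05) but not with an estimated correlation (adjusted p = 0.667), and with the repeated animals as fixed blocks 3 members were higher. Of 30 regulators of myoblast proliferation and differentiation 8 were higher and 2 lower (9 and 2 adjusted over the list alone): miR-31 (0.91), miR-222 (0.52) and miR-23a (0.37) were higher, and miR-29a (-0.19) and miR-29c (-0.26) lower. The leukocyte list had 3 of 8 higher (3 adjusted over the list alone), namely miR-146a, miR-146b and miR-155, and the smooth muscle and fibroblast list 3 of 9 higher (5 adjusted over the list alone), namely miR-199a-5p, miR-21-5p (0.32) and miR-143 (0.31). Lipid metabolism had 3 of 18 higher (3 adjusted over the list alone). Members higher and lower were 2 and 3 of 22 for insulin signalling (3 and 3 adjusted over the list alone), 2 and 2 of 12 for hypoxia and mitochondria, 1 and 1 of 10 for let-7, and 4 and 4 of 41 for miR-2284 and miR-2285, with the same counts adjusted over the list alone for the last 3. miR-92a was the only lower member of the miR-17-92 clusters, and miR-885 that of the liver list (1 of 12 and 1 of 3, and 1 and 2 adjusted over the list alone). The slow-fibre, erythrocyte, endothelium and neuron lists had 0 called members by edgeR in either direction, and so did miR-141, the tested epithelial miRNA (-0.04).

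The breed average called 69 of 318 miRNAs, 35 higher and 34 lower. With total-count scaling, which shifts the median of all miRNAs by 0.14, it called 40, 37 higher and 3 lower. The median of the imprinted cluster was then 0.41. Such scaling moves all miRNAs nearly alike, so a median above the shift is no added support for the cluster's difference. Among the miRNAs named, miR-127 stood at 0.41 (adjusted p = 0.0537), miR-215 at -0.48, miR-101 at -0.23, miR-15a at -0.20, miR-484 and miR-331-3p at -0.19 and miR-22-3p at -0.17, in the same direction but not called. With the animal as a random or fixed block, miR-215 (adjusted p = 0.0966 and 0.212) and miR-127 (0.0791 and 0.148) were not called. Without high-RFI Holstein-Friesian grass replicate 2, miR-215 was not called (-0.49, adjusted p = 0.0832) and miR-411a was (0.22, 0.0421). Without the 2 libraries far from their groups in miR-143, miR-215 (-0.54, adjusted p = 0.0678) and miR-127 (0.22, adjusted p = 0.057) were not called.

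On grass the breeds differed in 96 miRNAs, 47 higher and 49 lower in Holstein-Friesian steers (50 with total-count scaling, 47 and 3, where the median shifts by 0.20). miR-423-3p was lower by -0.43 ± 0.07 (adjusted p = 2.74e-05, 15 of 16) and miR-331-3p by -0.75 ± 0.15 (0.000328, 15 of 16), and both lost the call with total-count scaling. miR-152, a relative of miR-148a that targets a DNA methyltransferase, was 1.88-fold higher (0.91 ± 0.16, adjusted p = 3.03e-05, 15 of 16). The DLK1-DIO3 cluster had 13 of 26 members higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 2.27e-08, adjusted p = 0.384 with an estimated correlation). Among them miR-127 was higher by 0.40 ± 0.12 and miR-411a by 0.29 ± 0.11 (not called with the fixed block, adjusted p = 0.146), while miR-381 (0.12) did not pass. In the smooth muscle and fibroblast list 5 of 9 were higher (5 adjusted over the list alone; camera adjusted p = 0.0395, adjusted p = 0.533 with an estimated correlation), and 3 with limma-voom or the random block. Without the 2 libraries far from their groups in miR-143, both from Holstein-Friesian steers on grass, 2 were higher. Its most abundant members were miR-10b (-0.10, not called), miR-143 (0.47, not called with the random block, adjusted p = 0.061) and miR-21-5p (0.75 ± 0.16, adjusted p = 0.000837, 14 of 16). The miR-143 call rested on low-RFI Holstein-Friesian grass replicate 2, without which it stood at 0.27 (adjusted p = 0.0908), and at 0.19 (adjusted p = 0.241) without both.

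On concentrate 5 miRNAs differed between the breeds (3 with the random block): miR-206 (0.97 ± 0.22, 15 of 16), miR-11977 (1.04 ± 0.24, 15 of 16) and miR-147 (1.38) were higher, and miR-101 (-0.42 ± 0.09, 16 of 16) and miR-15a (-0.43) lower in Holstein-Friesian steers. miR-147 and miR-15a were named after their values were seen. With total-count scaling 2 were called, both higher, miR-206 and miR-11977. Without the concentrate libraries of the repeated steers only miR-101 was called, and miR-206 and miR-11977 had an adjusted p of 0.0501. The miR-17-92 clusters lay lower (camera adjusted p = 0.00556, adjusted p = 0.946 with an estimated correlation) with 0 members called by edgeR over all miRNAs and 2 adjusted over the list alone. miR-92a stood at -0.40, miR-25 at -0.44 and miR-19b at -0.58, and the erythrocyte miRNA miR-451 at -0.90 ± 0.52 (adjusted p = 0.35).

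Diet asked how muscle miRNAs of steers fed concentrate differ from those of steers fed grass in the preceding phase. The DLK1-DIO3 cluster was lower on concentrate almost throughout: 24 of 26 members fell and 0 rose (26 and 0 adjusted over the list alone), with a median log2 difference of -0.71 (interquartile range -0.80 to -0.58). miR-381 fell from 124 ± 37.3 to 55.0 ± 17.8 CPM (-1.18 ± 0.11, adjusted p = 1.70e-13), miR-127 from 1398 ± 373 to 796 ± 201 CPM (-0.80 ± 0.09, 2.1e-11) and miR-411a from 697 ± 145 to 399 ± 94.7 CPM (-0.80 ± 0.08; SD, n = 32 each). These 3, miR-380-3p (-0.91) and miR-410 (-0.84) were each lower in 32 of 32 concentrate libraries than the grass median. The list test held with either correlation (camera adjusted p = 1.61e-17, and adjusted p = 0.015 with an estimated correlation). The cluster fell in both breeds, with miR-381 at -1.11, miR-411a at -0.69 and miR-127 at -0.64 in Charolais and at -1.25, -0.91 and -0.95 in Holstein-Friesian steers. Called lower were 15 of 26 members in Charolais (18 adjusted over the list alone; median -0.59, camera adjusted p = 1.06e-07, adjusted p = 0.514 with an estimated correlation) and 24 of 26 in Holstein-Friesian steers (26 adjusted over the list alone; median -0.87, 2.8e-22, adjusted p = 0.00241 with an estimated correlation). With total-count scaling, which moves the median of all miRNAs by -0.26, the cluster's median was -0.9999 and 26 members were lower.

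Also lower on concentrate were miR-450b (-0.89 ± 0.13, adjusted p = 1.54e-07) and miR-424-5p (-0.86 ± 0.11, 9.57e-10), neighbours in an X-linked cluster, each in 29 of 32 libraries. miR-2285av had the largest difference (-2.29 ± 0.07, 32 of 32, with -2.37 in Charolais and -2.22 in Holstein-Friesian steers). It is among the 9 tested miRNAs whose fractional divisor differed between the phases, as is miR-2284h-5p, which had among the smallest p in each breed (1.21 ± 0.13 in Charolais and 1.19 ± 0.13 in Holstein-Friesian steers).

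Among miRNAs averaging 10 CPM or more, the largest rises on concentrate were in miRNAs of blood cells. miR-451, the most abundant miRNA of erythrocytes, averaged 3372 ± 3066 CPM on grass and 8912 ± 10294 on concentrate (SD, n = 32 each; 1.30 ± 0.37, adjusted p = 0.00526, above the grass median in 23 of 32). Its cluster partner miR-144 rose by 1.09 ± 0.37 (25 of 32), and miR-142-5p (0.69 ± 0.22, 24 of 32) and miR-142-3p (0.65 ± 0.19, 19 of 32), made in all haematopoietic cells, rose with them. In the leukocyte list 5 of 8 rose and 0 fell (5 adjusted over the list alone; 2 with no filter on low counts and 3 at 10 CPM or more), among them the myeloid miRNA miR-223 (0.81), and 2 of 4 in the erythrocyte and platelet list rose (2 adjusted over the list alone). In the miR-17-92 clusters 7 of 12 rose (8 adjusted over the list alone), led by miR-18a (0.81), miR-106a (0.70) and miR-93 (0.57 ± 0.14, 26 of 32), but the list test did not pass (camera adjusted p = 0.14). Within groups the members of those clusters followed miR-451, with a median Pearson r of 0.7097 (0.653 without the 2 libraries farthest in miR-451) and Spearman rho of 0.665. The permutation p was 1e-04 for each, the smallest the permutations can give, and 0.000533 and 0.00032 adjusted over 16 lists. With total-count scaling edgeR called 0 members of the leukocyte, erythrocyte and miR-17-92 lists higher in the diet average. The leukocyte median then stood at -0.01 in place of 0.27, a move of about the size of the shift of all miRNAs (-0.26).

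miR-1, the muscle miRNA that favours differentiation, rose by 0.47 ± 0.09 (adjusted p = 2.96e-05, 27 of 32). miR-103 (0.55 ± 0.13, 27 of 32) and its relative miR-107 (0.43), known to lower insulin sensitivity in liver and fat, also rose, as did miR-185 (0.55), miR-29b (0.45), miR-29c (0.28) and miR-10b (0.38 ± 0.15, adjusted p = 0.0355). miR-206 stood at 0.37 and lay at the threshold (adjusted p = 0.0554). It passed in several settings, among them DESeq2 (adjusted p = 0.0288), RLE factors (0.0340), TMM without the 3 most abundant miRNAs (0.0345) and the random block (0.0487). It did not pass with total-count scaling, limma-voom or the fixed block. miR-486 at 0.17, miR-133a at -0.06, miR-133b at -0.02, miR-208a at 0.34, miR-208b at -0.08 and miR-499 at -0.01 did not pass (miR-133a, at -0.31, and miR-208b, at -0.35, passed with total-count scaling), nor did miR-26a (-0.22) or miR-143 (-0.21). Of the 8 myomiRs 1 rose (1 adjusted over the list alone). All 8 of the largest rises at 10 CPM or more, from miR-451 to miR-1, lost the call with total-count scaling. They kept it with RLE factors and with TMM without the 3 most abundant miRNAs. Total counts depend on the share of miR-10b, whose group means were 52.5 to 54.8% on grass and 58.3 to 64.0% on concentrate. Whether that share accounts for the lost calls was not tested. With miR-451 as a covariate, miR-103 stood at 0.09 (adjusted p = 0.436), miR-185 at 0.03 (0.889) and miR-93 at 0.08 (0.473), none called. The rises of these miRNAs can therefore not be set apart from that of miR-451.

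In the insulin and glucose list 8 of 22 rose and 0 fell (8 and 0 adjusted over the list alone), including miR-103, miR-107, miR-29b and miR-223. In the miR-2284 and miR-2285 family 10 rose and 1 fell of 41 (10 and 1 adjusted over the list alone), among which the rises of miR-2284h-5p, miR-2285g and miR-2285au and the fall of miR-2285av are of miRNAs whose fractional divisor differed between the phases. With total-count scaling the medians of these 2 lists stood at -0.26 and -0.02 in place of 0.01 and 0.24, about the shift of all miRNAs (-0.26). Members up and down were 4 and 5 of 30 for myoblast regulators (4 and 7 adjusted over the list alone), 3 and 4 of 18 for lipid metabolism (3 and 5), 2 and 3 of 12 for hypoxia and mitochondria (2 and 3), 2 and 0 of 10 for let-7 (1 and 0), 1 and 2 of 6 for endothelium (1 and 2), 1 and 1 of 9 for smooth muscle and fibroblast (1 and 1), 2 and 0 of 3 for liver (2 and 0) and 0 and 1 of 4 for neuron (0 and 1), each bracket adjusted over the list alone. The called let-7a-3p (0.30), of the let-7 and insulin lists, and miR-181a (-0.18), of the myoblast list, also had a divisor that differed between the phases. In the slow-fibre list 0 of 2 were called, and the epithelial miR-141 stood at 0.57 (adjusted p = 0.0502). Besides the imprinted cluster, no list passed its test in the diet average.

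**Figure D3:**
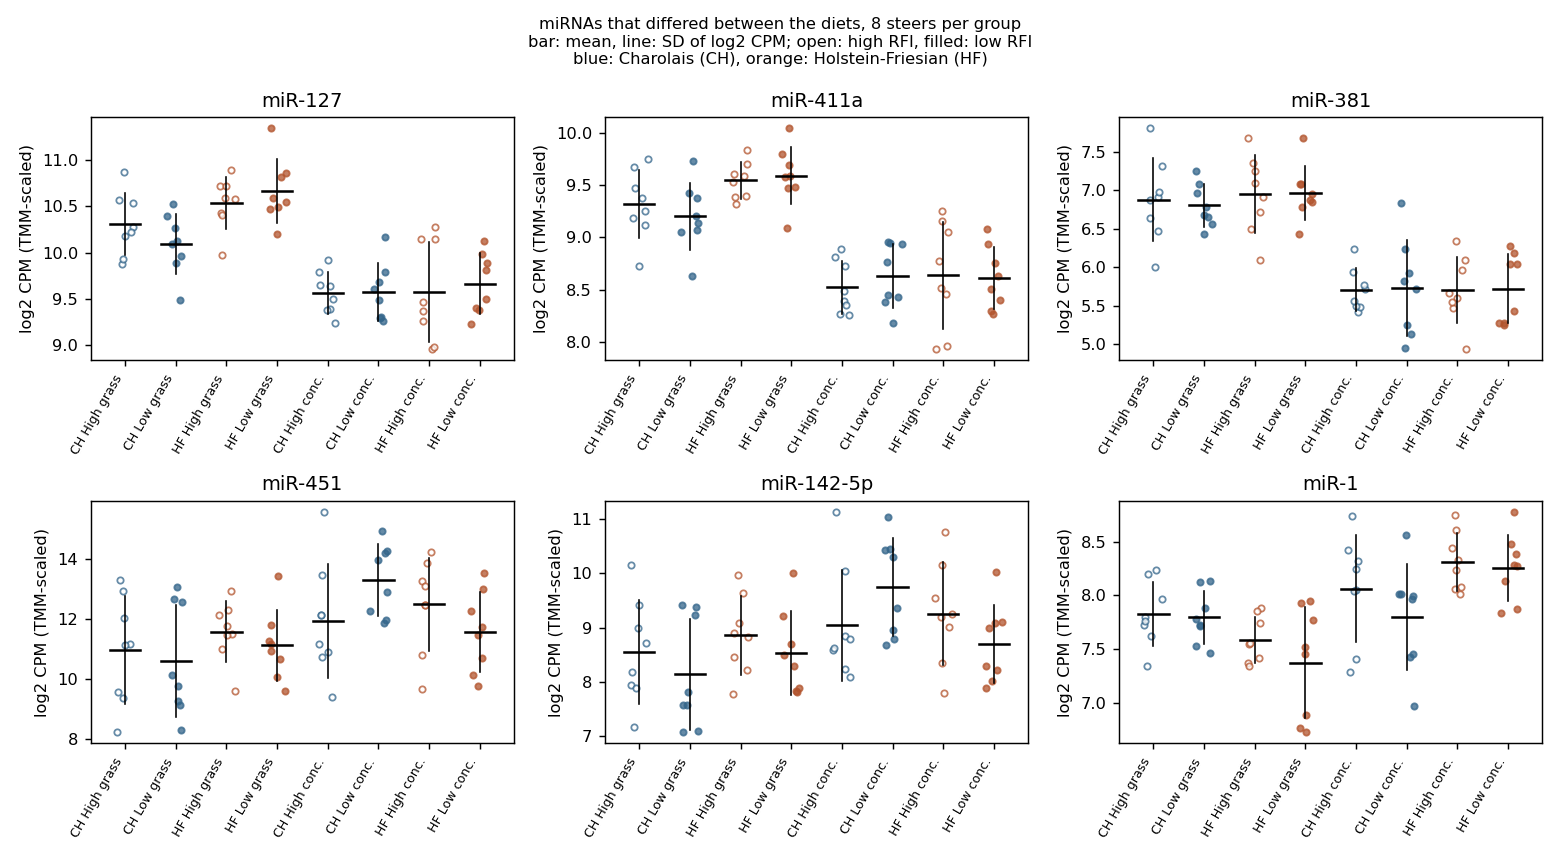
Log2 CPM (TMM-scaled) of miR-127, miR-411a, miR-381, miR-451, miR-142-5p and miR-1 in each library by group, with 8 steers per group and points open for high and filled for low RFI, where bars mark group means and lines the SD. The first 3 were lower in 32 of 32 concentrate libraries than the grass median, and miR-451, miR-142-5p and miR-1 were higher in 23, 24 and 27 of 32, calls that are lost with total-count scaling.

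The diet average called 108 miRNAs, 57 higher and 51 lower, and 125 with total-count scaling, 7 higher and 118 lower. In Charolais steers 66 were called, 30 higher and 36 lower (42 with total-count scaling, 2 and 40; 78 with RLE size factors, 44 and 34). There miR-451 rose by 1.76 (adjusted p = 0.0106), and 7 of 12 members of the miR-17-92 clusters rose (9 adjusted over the list alone; camera adjusted p = 0.00747, adjusted p = 0.834 with an estimated correlation; 1 member with total-count scaling, 3 with limma-voom and 3 with no filter on low counts). Among them was miR-25 (0.65 ± 0.20, 12 of 16), while miR-92a (0.24) and miR-19b (0.81) did not pass. In Holstein-Friesian steers 77 were called, 34 higher and 43 lower (94 with total-count scaling, 6 and 88), and miR-451 stood at 0.84 (adjusted p = 0.239).

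The interaction of breed with diet asked which diet differences were unlike in the breeds, and 11 miRNAs passed, 7 with a higher and 4 with a lower difference in Holstein-Friesian steers. miR-423-3p fell by 0.25 in Charolais and rose by 0.25 in Holstein-Friesian steers (interaction 0.50 ± 0.10, adjusted p = 0.000667). miR-152 stood at 0.33 (not called) in Charolais and fell by 0.75 in Holstein-Friesian steers (interaction -1.08 ± 0.22, 0.000667). miR-380-3p fell in both, by 0.49 and 1.32 (interaction -0.83 ± 0.16, 0.000667). miR-1, named after its values were seen, rose by 0.78 in Holstein-Friesian steers and stood at 0.17 (not called) in Charolais, with an interaction of 0.62 (adjusted p = 0.0373). The imprinted cluster as a list fell further in Holstein-Friesian steers (camera adjusted p = 4.97e-06), but not with an estimated correlation (adjusted p = 0.669), and 2 of its members passed alone, while miR-127 (-0.31), miR-411a (-0.22) and miR-381 (-0.14) did not. With total-count scaling 1 miRNA passed, with a lower difference, and with RLE size factors 11, 5 higher and 6 lower.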

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

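The tests of other scalings, the test of the fractional counts and the fits with miR-451 as a covariate or without single libraries were chosen only after the results had been seen, while the others in this part were written down before.

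The fall of the DLK1-DIO3 cluster on concentrate (24 of 26 members, median -0.71) was weighed against scaling, different animals and time. At least 22 of the 26 members were called lower under each of 3 other scalings, but none of these could have undone the fall. They shifted all miRNAs by a median of 0.022 (RLE), 0.021 (TMM without the 3 most abundant) and -0.26 (total counts). A scaling factor moves all miRNAs of a library alike, and the median of all tested miRNAs was 0.014 against -0.71 for the cluster. That gap, not the count of calls, argues against scaling as the whole cause. A different choice of steers as the whole cause is argued against less firmly: in the 5 steers sampled in both phases the members' median was below 0 in 5 of 5, with a mean of -0.534 ± 0.337 (SD, n = 5) and an exact two-sided sign-flip p of 0.0625, the smallest that 5 steers allow, but 1 steer stood at -0.16 with all miRNAs at -0.13, another at -0.20 with 15 of 26 members below 0, and the steer with the largest fall (-0.89) was of high RFI on grass and low RFI on concentrate. Chance can be excluded at the level of 100 splits, since 1 of them, the real one, called as many members lower, and the highest other called 0. These splits did not keep the pairs of libraries from the 5 repeated steers. Feed cannot be told apart from the order of the phases or the age of the steers, because 0 diets were fed in more than 1 phase. Nor can feed be told apart from processing or quantification that differed between the phases, as the fractional divisors of some miRNAs did. A response to the feed stays a hypothesis.

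The rise of blood-cell miRNAs on concentrate (7 called members of the erythrocyte and leukocyte lists) may come from more blood RNA in those libraries. The lists were fixed in advance, but these 7 of 12 tested members were picked by their diet calls. Over all members besides miR-451, the median Pearson r with it was 0.0433 in the erythrocyte and platelet list and 0.336 in the leukocyte list. miR-144 is the cluster partner of miR-451 and miR-142-5p and miR-142-3p are arms of the same precursor, so their relations overlap. Within groups miR-451 went with the other 6 at a median Pearson r of 0.895 (0.877 without the 2 farthest of 64 libraries) and Spearman rho of 0.893, permutation p 1e-04 for each, the smallest the permutations can give, and of these 6 relations miR-150 (r 0.474, rho 0.432, adjusted p = 0.00048 and 0.00108) and miR-342 (r 0.109, rho 0.0983, adjusted p = 0.427 and 0.460) were the weakest. miR-451 ranged from 298 to 49098 CPM between libraries, and with it as a covariate 0 of the 6 stayed called (miR-144 went from 1.09 ± 0.37 to -0.12), against 28 of 56 rises, these 6 among them, and 41 of 51 falls. For miR-342, which hardly followed miR-451, the lost call says little on blood RNA. Scaling stays open for the calls but less so for the direction, since total-count scaling, which shifts all miRNAs by -0.26, called 0 of the 7 with their median still at 0.34, while RLE factors and TMM without the 3 most abundant miRNAs called 7 (0.71 and 0.70). All 12 tested members of both lists were counted in these muscle libraries, of which miR-451 (6142 CPM) and miR-142-5p (584 CPM) were the most abundant. Feed cannot be told apart from the order of phases or from processing that differed between them, as 0 diets were fed in more than 1 phase.

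The 9 tested miRNAs whose fractional divisor differed between the phases had a median absolute diet difference of 0.382, against 0.185 for the 31 tested fractional miRNAs with a divisor of the same size in both phases (one-sided permutation p = 0.0130). Of the 9, 6 were called and of the 31, 8. Quantification that differed between the phases is a candidate explanation for the diet differences of the 6, among them miR-2285av, miR-2284h-5p, miR-2285g and miR-2285au. Their divisors on grass and concentrate were 9 and 8, 2 and 1, 3 and 1, and 1 and 3, in that order. The differing divisor of miR-2285au rests on 1 concentrate library with a fractional value, and that of let-7a-3p (1 and 2) on 5. Whether these divisors would give differences of that size or sign was not tested. No biological explanation was tested for this pattern.

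Single libraries stood far from the other 7 of their group in 6 of 72 groups of values examined, where chance gives about 1 in 20, or 3.6. High-RFI Holstein-Friesian grass replicate 1 had a miR-10b share of 19.3% and a TMM factor of 2.43. Low-RFI Charolais grass replicate 5 had a TMM factor of 1.88. miR-143 reached 50025 CPM in high-RFI Holstein-Friesian grass replicate 2 and 110805 CPM in low-RFI Holstein-Friesian grass replicate 2, and the breed call of miR-143 on grass was lost without the latter. miR-150 reached 41.2 CPM in low-RFI Holstein-Friesian concentrate replicate 5.

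The diet difference was unlike in the breeds, by the interaction test, for 11 miRNAs. It was higher in Holstein-Friesian steers for miR-423-3p (0.50), miR-378b (0.84), miR-365-3p (0.60), miR-331-3p (0.81), miR-2285ba (1.01), miR-378d (0.73) and miR-1 (0.62), and lower for miR-380-3p (-0.83), miR-152 (-1.08), miR-21-5p (-0.86) and miR-376b (-1.06). miR-2285b, left out of the tests for its 3 empty cells, had counts up to 56 in the 61 libraries with a value (median 19).

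Other splits of the libraries into groups of the same sizes, 100 each with the real split included, were set against each count of calls. Chance can be excluded at that level for the breed average (69 calls, 1 split as large, highest other 13), breed on grass (96, 1, 28), the diet average (108, 1, 28), diet in Charolais (66, 1, 37) and diet in Holstein-Friesian (77, 1, 14). It can be excluded as well for the DLK1-DIO3 members higher by breed on grass (13, 1, 4). It is left open for breed on concentrate (5, 4, 30) and the breed and diet interaction (11, 3, 57), where fewer than 1 in 20 splits were as large but single ones called several times the real count, and total-count scaling left 2 and 1 calls. For the DLK1-DIO3 members in the breed average (7, 1, 2) it is left open, since with the repeated steers as fixed blocks 3 were higher, near the highest other. The splits of breed moved the 2 libraries of a repeated steer apart, and those of diet could place both on the same diet. For the RFI comparisons the real split called 0 by edgeR, so that all 100 splits called at least as many by construction, and the count says nothing on chance. Their highest others were 16 and 35 in Charolais on grass and concentrate, 20 and 1 in Holstein-Friesian on grass and concentrate, 4 in the average, 45 for RFI with breed and 25 for RFI with diet. Splits that call several times the real count, as 57 against 11 and 35 against 0, point to a structure of the samples. A candidate is miR-451, whose log2 CPM had an SD of 1.52 within groups. The first principal component (22.2% of the variance between libraries) was highest in high-RFI Charolais concentrate replicate 3 (14.0, miR-451 at 49098 CPM). It was lowest in high-RFI Charolais grass replicate 3 (-8.17, miR-451 at 298 CPM). Whether miR-451 accounts for these splits was not tested, and only the diet average was fitted with it as a covariate.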

How the results depend on the processing

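The fits of breed and diet without single libraries, those without the 2 libraries far from their groups in miR-143, without the miRNAs whose fractional divisor differed and with miR-451 as a covariate, and the counts of list members under each setting, were chosen after seeing the data, and the others were planned. Of the counts of calls, those of RFI in Charolais, RFI in Holstein-Friesian on grass, the RFI average and both RFI interactions were 0 by edgeR in every setting, DESeq2 and limma-voom included (unadjusted counts stand with the results). For RFI in Holstein-Friesian steers on concentrate, 2 passed without the concentrate libraries of the repeated steers, 3 at a threshold of 0.10, and 0 to 4 when single libraries were left out (4 without high-RFI replicate 1, 1 without replicate 5 and 1 without replicate 7). The fit without the repeated steers' concentrate libraries also left out high-RFI replicate 1. Total-count scaling gave 40 calls for the breed average, 50 for breed on grass, 2 for breed on concentrate, 42 for diet in Charolais and 1 for the interaction. Asking for 1.5-fold as well left 10 for the breed average, 31 on grass, 3 on concentrate, 42 for the diet average and 48 for diet in Holstein-Friesian. A mean of at least 10 CPM left 2 for breed on concentrate, 68 for the diet average and 41 for diet in Charolais, with fewer miRNAs tested. Breed on concentrate gave 3 with limma-voom, 3 with the animal as a random block, 1 without the concentrate libraries of the repeated steers and 10 at a threshold of 0.10. The interaction gave 7 without those libraries and 28 at a threshold of 0.10. With miR-451 as a covariate the diet differences of miR-144 (-0.12) and miR-142-5p (-0.0216) turned sign, uncalled. That fit also ended the diet calls of miR-142-3p, miR-93, miR-185 and miR-103 and added that of miR-206 (0.51, adjusted p = 0.0150). For the other changes the cause was not tested.

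All other counts of called miRNAs in the 14 comparisons stayed within 1.5 times the reported ones. Similar counts could still hold different miRNAs. With total-count scaling the diet average shared 58 of its 125 calls with the reported 108, and diet in Holstein-Friesian 49 of its 94 with the reported 77. With no filter on low counts the diet average called 113, 40 higher and 73 lower, and 79 of these were among the reported calls. Without single Holstein-Friesian grass libraries (high-RFI replicates 1 and 2 and low-RFI replicate 2, each in turn) the breed average called 66 to 78 and breed on grass 88 to 98, and without the 2 libraries far from their groups in miR-143 60 and 90. Without high-RFI replicate 1 breed on concentrate called 6, the diet average 121, diet in Charolais 73, diet in Holstein-Friesian 84 and the interaction 10. Without the miRNAs of differing divisor the diet average called 111, and with miR-451 as a covariate 96. Of 115 single miRNA differences named, total-count scaling ended 22 calls and added 2, RLE factors ended 0 and added 1, DESeq2 ended 0 and added 3, limma-voom ended 4, the fit with no filter on low counts ended 6, that without the concentrate libraries of the repeated steers ended 4 and added 2, and the animal block, besides the calls given with the results, changed no other call. Leaving out the 2 libraries far from their groups in miR-143 ended 3 of 37. Summing repeated names gave no value, as no name was repeated, and a fit of only the groups compared gives none for comparisons that use all 8 groups. At 8 steers a group, RFI in Holstein-Friesian steers on concentrate, the RFI comparison simulated, could have missed differences of 2-fold or less, since 37% of simulated 1.5-fold and 77% of 2-fold changes were recovered.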

Other observations

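The miRNAs of this part, the relations of the lists to miR-451 and the fit with miR-451 as a covariate were tests chosen only after the results had been seen. Together with miR-424-5p and miR-450b, miR-450a (-1.05 ± 0.13, adjusted p = 3.64e-10), miR-542-5p (-1.04 ± 0.13, 3.64e-10) and miR-424-3p (-1.03 ± 0.22, 0.000163) were lower on concentrate. These single miRNAs were picked by their values, and their cluster was not among the lists and was not tested as one. In the lipid metabolism list, miR-335 (-0.46 ± 0.14), miR-224 (-0.41), miR-130a (-0.35) and miR-27b (-0.17) fell on concentrate, of which miR-130a and miR-27b repress the adipogenic factor PPARG, while miR-103, miR-107 and miR-144 rose.

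Among miRNAs of the miR-378 name, which were not tested as a list, miR-378b (0.74) and miR-378d (0.82) rose on concentrate in Holstein-Friesian steers and stood at -0.11 and 0.09 in Charolais, where neither was called. The more abundant miR-378 stood at 0.18 and -0.24 and miR-378c at -0.01 and -0.16, called in neither breed. In Holstein-Friesian steers miR-21-5p fell by 0.80 and stood at 0.06 in Charolais.

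Within groups, the relations to miR-451 were computed for 16 lists over 64 libraries. Over all other tested miRNAs the median Pearson r with miR-451 was -0.152. The permutation p-values set each list against no relation and not against this background. The 3 other members of the erythrocyte and platelet list had a median Pearson r of 0.0433 (rho 0.00609, adjusted p = 0.724 for r and 0.948 for rho, 0.101 without the 2 farthest libraries), with miR-144 at 0.950 and the lowest at 0.0279. The miR-17-92 clusters had a median Pearson r of 0.7097 and the leukocyte list 0.336 (Spearman rho 0.665 and 0.344, adjusted p = 0.000533 and 0.000914 for r and 0.00032 each for rho, 0.653 and 0.315 without the 2 farthest libraries). The myomiRs stood at -0.334 and the let-7 family at -0.374 (rho -0.397 and -0.424, adjusted p = 0.000533 each for r and 0.00032 each for rho, -0.290 and -0.353 without the 2 farthest libraries), and the DLK1-DIO3 cluster at -0.147 (rho -0.161, adjusted p = 0.126 for r and 0.0849 for rho, -0.0655 without the 2 farthest libraries). With miR-451 as a covariate, miR-106a (0.58, adjusted p = 0.0286) alone of the 7 risen members of the miR-17-92 clusters stayed called.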
